A study of Homo sapiens with 18 samples.

How the data were processed

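RNA of 18 samples was hybridised to 2-colour expression arrays, 1 array per sample. Per the labels, the Cy5 channel held the test sample and the Cy3 channel a common pooled reference, with amplified cDNA in both. The samples were HUVEC, primary human umbilical vein endothelial cells, and Jurkat, an established human T cell leukemia line, alone or in co-culture, each cell type irradiated or not, at 1 h or 4 h. The growth, treatment and extraction protocols, the irradiation dose and the cells from which RNA was taken after co-culture are not given in the sources used here.

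The deposited values were taken as log10 ratios of the sample over the reference, normalized by the authors so that every array has a median of 0. The method is not stated. The labels give the direction of the ratio but not its base. Base 10 was inferred from the values. Among unnamed probes, a set of 32 was picked by low medians and a set of 37 by high medians. The sets had medians of -0.697 and 1.05, 56-fold apart in base 10 and 3.36-fold apart in base 2. The true ratio between them is not given, so they do not settle the base. The values ran from -2.65 to 3.36. All values were multiplied by 3.322 to give log2 ratios, so every log2 value would shrink by that factor if the base were 2. Directions and tests would stay as they are.

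Of 45220 probes, 44495 had values, and between 23.8% and 32.1% of these were exactly 0 on an array. An exact 0 was counted as no value, a choice made after the values had been seen; keeping the zeros as values was run as an alternative. A probe was used where it paired with exactly 1 gene, and 102 probes of Y-linked and X-inactivation genes were left out. The probes of a gene were averaged after each array had been centred on its median. A gene was tested where it had values on at least 15 of the 18 arrays and in every group compared, which left up to 13714 genes per comparison. Because a probe at exactly 0 drops out of its gene's average, that average can rest on different probes on different arrays. An alternative used only probes with a value on all 18 arrays.

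Groups came from the sample labels: the cells named, their order, the irradiation of each and the time. Samples whose labels name HUVEC first are called HUVEC-first co-cultures here, and those that name Jurkat first Jurkat-first co-cultures. The labels do not explain the order. The sample titles carry 4 dates, called A to D. The labels do not say whether replicates were separate cultures. With 1 to 4 arrays per group, the number of arrays limits the precision.

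One limma model (limma 3.58.1, R 4.3.3) with a mean for each of the 12 groups was fitted to all 18 arrays, leaving 6 residual degrees of freedom, all of them from HUVEC-first co-cultures and HUVEC alone. Groups of 1 array, among them every group that names Jurkat first, are therefore assumed to vary like those. Tests were limma's moderated test after empirical Bayes, two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. In the Jurkat-first co-cultures the 4 arrays were read as a 2 by 2 layout of main effects. Differences between responses were tested as interaction contrasts. A pair of comparisons of 1 array against 1 array were planned as values only and were not tested.

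Before the data were examined, 18 lists of genes were written down, as were the groups, the comparisons, the test and threshold, all alternatives that are not named as later ones, and the rule for naming genes. The lists cover p53 targets, DNA repair, S phase genes, G2 and mitosis genes (G2/M), NF-kB targets with cytokines and chemokines, immediate early genes, interferon response, T cell activation, endothelial activation, TGF-beta and BMP targets, stress and unfolded protein response, hypoxia and glycolysis, sterol synthesis, ribosomal proteins, and markers of endothelial, T, mesenchymal, and myeloid and B cells. They hold 383 genes, of which 306 were tested. Each list was compared with all other genes by cameraPR on z scores with a preset correlation of 0.01, adjusted over lists and comparisons together, and again with a correlation estimated from the residuals; fry was run beside it. A list is called where the preset-correlation test passed. Counts over a list's own members are given as adjusted over all genes and as adjusted over the list alone.

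The naming rule took, in each comparison, the up to 10 genes with the largest rise and fall past the threshold whose groups did not overlap (5 and 5 where a side had 1 array, and in interactions and 2 by 2 effects), from genes with a symbol. Where fewer than 3 passed, the 5 highest and 5 lowest by moderated test were taken and are given as not passing, and where no test was run, the 5 highest and 5 lowest differences. Members of the lists may be named in any comparison. Some of the genes so selected are left unnamed for length.

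The alternatives were quantile normalization, only probes valued on all 18 arrays, no minimum number of arrays, a fit of the compared groups alone, the date as a random block or fixed term, array weights, robust empirical Bayes, a cell marker score as a covariate (mean endothelial minus mean T cell marker), and each array of a replicated group left out in turn. Alternatives chosen after the data had been seen were zeros kept as values, centring on probes never at 0, arrays of date D only, and leaving out the arrays of date B with replicate 2 of irradiated HUVEC alone at 1 h. The fit was tested on simulated data with the same layout and the same spread per gene. The simulated noise was normal, independent between genes and equal in all groups, with no differences by date or cell mixture. It therefore does not show how the fit behaves where these occur. With no change simulated it made 0 calls. Of genes changed by 2 on the log2 scale it recovered 68.7% for both cell types irradiated at 1 h, 59.7% at 4 h and 34.8% for the difference between these responses. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.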

Results

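The 18 arrays fall into 12 groups. Among HUVEC-first co-cultures at 1 h, 4 arrays had both cell types irradiated, 2 had neither irradiated and 1 had only HUVEC irradiated. At 4 h, 2 arrays had neither irradiated and 1 had both. HUVEC irradiated alone was measured on 2 arrays at 1 h and 1 array at 4 h, and Jurkat irradiated alone on 1 array at 1 h. Jurkat-first co-cultures at 1 h had 1 array each of neither, only Jurkat, only HUVEC and both irradiated. The median correlation of replicate arrays was 0.767, with 0.507 for the 2 arrays of HUVEC irradiated alone at 1 h. The median correlation of arrays naming HUVEC first or alone with arrays naming Jurkat first or alone was 0.346. Over the 18 lists and 12 tested comparisons, 61 of 216 list tests were called with the preset correlation, 4 passed by fry and 0 passed with an estimated correlation, where the smallest adjusted p was 0.051.

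Markers of the cell types differed widely between arrays, also within groups. The mean log2 ratio of T cell markers was 5.01 in the co-culture with only HUVEC irradiated, between 1.09 and 4.79 in the 4 HUVEC-first co-cultures with both irradiated at 1 h, and 0.84 and 1.25 in the 2 with neither. HUVEC irradiated alone gave 0.11 on replicate 1 and 2.96 on replicate 2 at 1 h, so replicate 2 carried T cell transcripts although its label names HUVEC only. At 4 h HUVEC irradiated alone gave 1.11, as high as some co-cultures, so this mean does not separate HUVEC alone from co-culture. The mean of endothelial markers was -2.21 in the co-culture with only HUVEC irradiated and between 0.84 and 1.17 in the 4 Jurkat-first co-cultures. Jurkat alone was near 0 for both lists, at 0.15 for endothelial and 0.25 for T cell markers. Markers of fibroblasts and smooth muscle also varied, from 0.09 to 2.39.

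**Figure D1:**
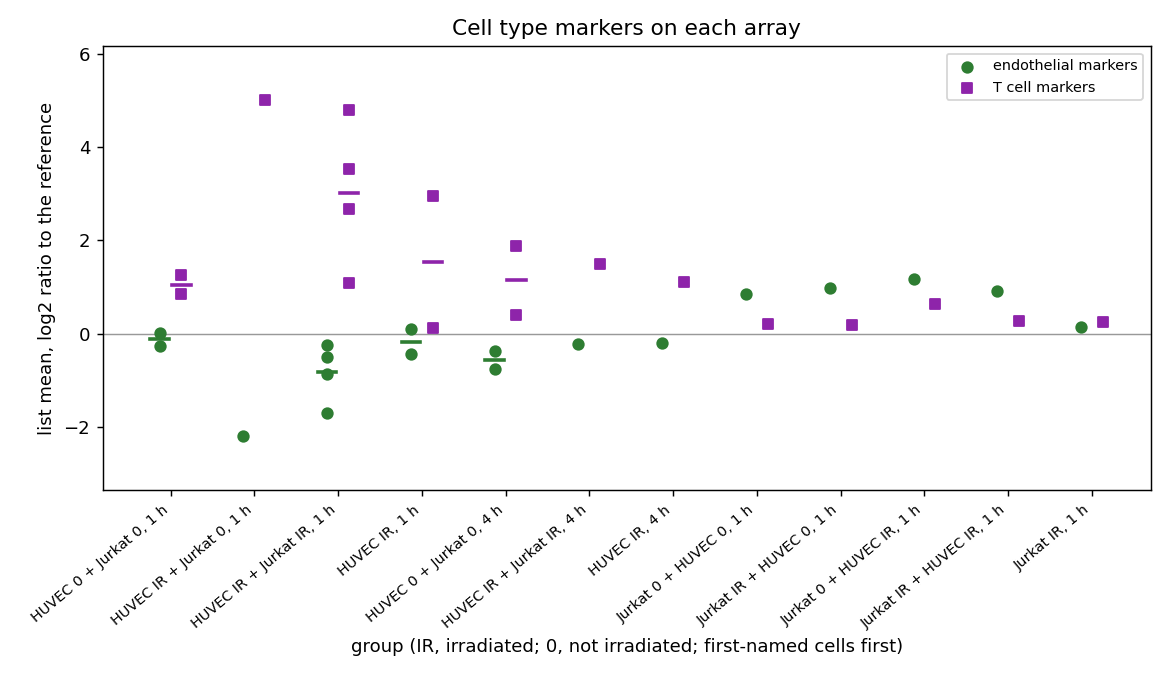
Mean log2 ratio (sample over reference) of endothelial and T cell markers on each of the 18 arrays, 1 point per array and list, with arrays placed by group and a line at the mean of each group of more than 1 array. T cell markers reach 5.01 where only HUVEC was irradiated, and replicates 1 and 2 of HUVEC irradiated alone at 1 h lie at 0.11 and 2.96.

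Irradiation of both cell types, compared with neither, in HUVEC-first co-cultures at 1 h (4 arrays against 2), raised direct targets of the transcription factor p53 as a list. Of 27 measured targets 22 were higher and 5 lower, with a mean log2 change of 0.53 (adjusted p = 1.56e-08, or 0.687 with an estimated correlation), and 8 passed upward when adjusted over the list alone. Among the 8 were BBC3, which encodes a pro-apoptotic BCL2 family protein, at 2.34 ± 0.245 (SE), the stress cytokine GDF15 at 1.73 ± 0.428, the p53 ubiquitin ligase MDM2 at 1.54 ± 0.267 and SESN2 at 1.32 ± 0.22. The mean of the list was 0.51, 0.60 and 0.66 on replicates 1, 3 and 4 with both irradiated and -0.04 on replicate 2, the array of date B, against -0.09 and -0.06 with neither irradiated. Arrays of date D alone gave a list change of 0.69. Over 18 alternatives the list change lay between 0.46 and 0.79. G2/M genes were lower, at a mean of -0.24 (18 of 23 lower, adjusted p = 0.00146, or 0.722 with an estimated correlation, 0 over the list alone).

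No single gene passed in that comparison: limma called 0 of 13714, with 901 at an unadjusted p under 0.05 and a smallest adjusted p of 0.158, that of BBC3. The genes highest by test beside BBC3 and SESN2 were GALNT18 at 1.75 ± 0.244 and the muscle ubiquitin ligase gene FBXO32 at 1.19 ± 0.198, and the lowest included ELN, which encodes elastin, at -0.83 ± 0.138 (adjusted p = 0.568 for these). Leaving out replicate 2 of the non-irradiated co-cultures gave 1 called gene. The cell markers moved as well: all 13 measured T cell markers were higher, by a mean of 1.52 (adjusted p = 0.00342, or 0.746 with an estimated correlation). All 18 endothelial markers were lower, at -0.71 (adjusted p = 0.000141, or 0.772 with an estimated correlation), or -0.41 without replicate 2 of the irradiated arrays. S phase genes were higher by 0.17 (20 of 24, adjusted p = 0.0159, or 0.802 with an estimated correlation). Stress and unfolded protein response genes were higher by 0.21 (14 of 20, adjusted p = 0.0327, or 0.687 with an estimated correlation). The S phase call was lost without irradiated replicate 2 (0.057) and without non-irradiated replicate 1 (0.13), and its value was -0.052 with the marker score as a covariate. The T cell call was lost with only probes valued on all 18 arrays (0.83). Over 18 alternatives the S phase call was lost in 7 and the stress call in 4. The stress call was lost without irradiated replicates 3 (0.18) or 4 (0.23) or non-irradiated replicate 2 (0.21), and after quantile normalization (0.21).

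**Figure D2:**
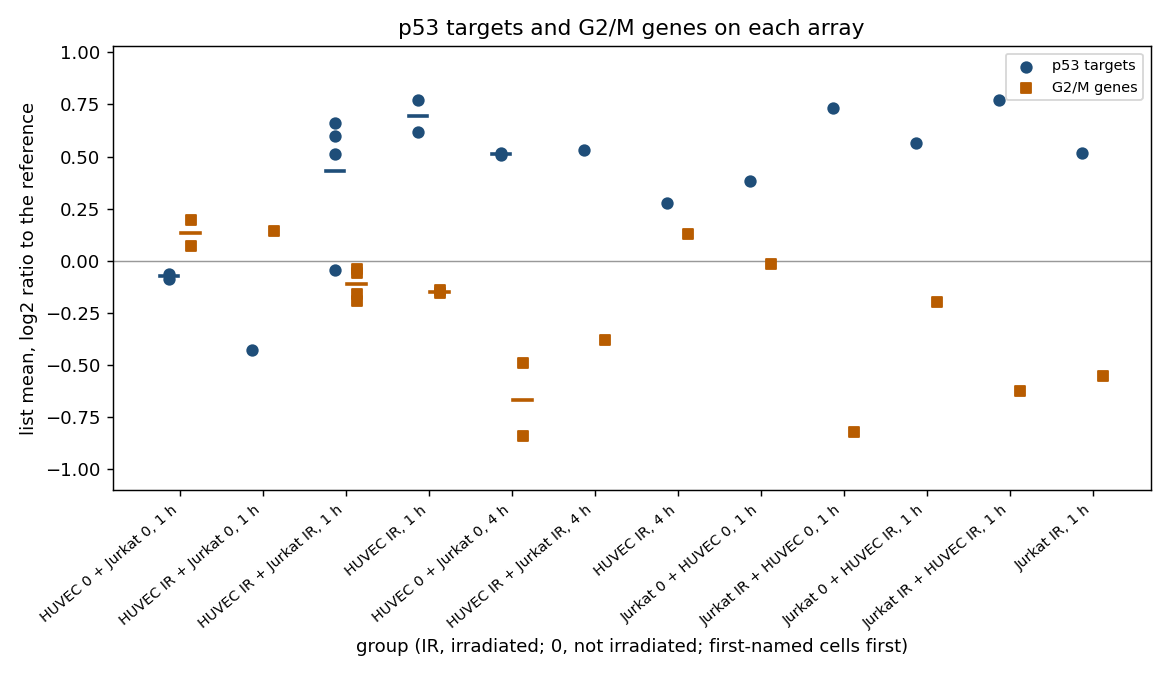
Mean log2 ratio (sample over reference) of p53 targets and of G2/M genes on each of the 18 arrays, 1 point per array, placed by group, with a line at the mean of each group of more than 1 array. In HUVEC-first co-cultures at 1 h, p53 targets lie at -0.09 and -0.06 without irradiation and at 0.51, -0.04, 0.60 and 0.66 with it, and at 4 h at 0.51 and 0.52 without and 0.53 with it.

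At 4 h the same irradiation, measured on 1 array against 2 of the same date, left p53 targets with a mean change of 0.05 (16 of 27 higher, adjusted p = 0.839). G2/M genes were higher by 0.29 (20 of 23, adjusted p = 0.00178, or 0.722 with an estimated correlation, 0 over the list alone), a call lost without non-irradiated replicate 1 (0.11) and raised to 0.46 without replicate 2. The list of myeloid and B cell markers was lower, at -1.59 (6 of 8 lower, adjusted p = 0.0212, or 0.24 with an estimated correlation), with 1 gene past adjustment over the list alone, the B cell receptor gene CD79B at -3.97 ± 0.808. That shift came from non-irradiated replicate 1, without which it was 0.50, and it was -2.58 without replicate 2. It was also no longer called with only probes valued on all 18 arrays (-0.85), in a fit of the compared groups alone (-0.82) and with zeros kept as values (-0.59). limma called 0 of 13571 genes, with 1023 at an unadjusted p under 0.05. Highest by test were ZNF26 at 1.44, AASDH at 1.18 and EIF2AK2, the interferon-induced kinase PKR, at 1.12 ± 0.208, and lowest was AKNA at -3.85 ± 0.429, all not passing (smallest adjusted p = 0.252). The average of AKNA rests on different probes on different arrays.

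The response at 4 h differed from that at 1 h in 4 lists, tested as an interaction. The p53 response was smaller at 4 h, with a difference of -0.48 (21 of 27 lower, adjusted p = 0.00268, or 0.765 with an estimated correlation), with 2 genes past adjustment over the list alone, BBC3 at -2.73 ± 0.423 and MDM2 at -1.98 ± 0.461. The G2/M response was higher by 0.53 (20 of 23, adjusted p = 0.000138, or 0.687 with an estimated correlation). Endothelial markers differed by 1.02 (18 of 18, adjusted p = 0.00327, or 0.802 with an estimated correlation). Myeloid and B cell markers differed by -1.87 (6 of 8 lower, adjusted p = 0.0351, or 0.247 with an estimated correlation). The last was 0.11 without 4 h non-irradiated replicate 1 and -2.86 without replicate 2, with its call also lost without irradiated replicates 1 (-1.80) or 2 (-1.72), and in 7 of 19 alternatives in all, among them the marker score as a covariate (-0.90). limma called 0 of 13569 genes with 1438 at an unadjusted p under 0.05, and 1 gene without 1 h non-irradiated replicate 2. ELN at 1.72, PAFAH2 at 1.90 and GALNT18 at -3.40 were among the farthest by test (adjusted p = 0.458). Time and date coincide here, so the dates cannot be told apart from the times.

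Irradiated HUVEC with irradiated Jurkat at 1 h (4 co-culture arrays) had higher NF-kB targets, cytokines and chemokines as a list than irradiated HUVEC alone (2 arrays). All 22 measured members were higher, with a mean log2 change of 1.30 (adjusted p = 5.23e-12, or 0.24 with an estimated correlation), and 11 passed when adjusted over the list alone. These included the chemokine genes CCL2 at 2.53 ± 0.642 and CXCL1 at 2.18 ± 0.517, and NFKBIA at 2.14 ± 0.397 and TNFAIP3 at 2.19 ± 0.517, which encode feedback inhibitors of NF-kB. Over 18 alternatives the list change lay between 0.78, without HUVEC alone replicate 1, and 1.98, without its replicate 2, and passed the preset-correlation test in all of them. Arrays of date D alone gave 1.46. The list's mean was 0.29 and 1.28 on the 2 arrays of HUVEC alone, between 1.61 and 2.26 in the 4 co-cultures, and 1.92 and 2.21 in the co-cultures with neither cell type irradiated. The 2 arrays of HUVEC alone correlated at 0.507. Replicate 2 correlated at 0.858, 0.777, 0.862 and 0.781 with co-culture replicates 1 to 4, closer than with replicate 1. B-lineage genes had means of 2.06 and 4.56 on HUVEC alone and 4.17 to 5.18 in the co-cultures. An effect of Jurkat cannot be told apart from other cell content. TGF-beta and BMP targets were higher by 1.04 (8 of 11, adjusted p = 0.000311, or 0.687 with an estimated correlation), 4 of them when adjusted over the list alone, among them HEY1 at 2.38 ± 0.597 and ID2, which encodes an inhibitor of helix-loop-helix transcription factors, at 2.12 ± 0.606. With zeros kept as values or no minimum number of arrays this list was at 0.58 and no longer called.

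**Figure D3:**
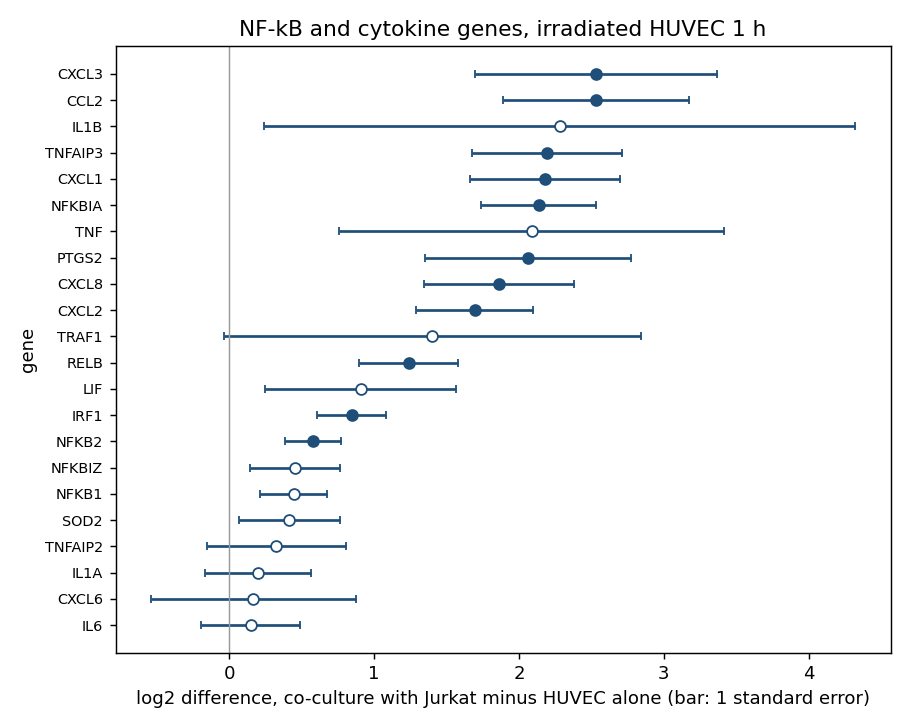
Log2 difference of the 22 measured NF-kB target, cytokine and chemokine genes between irradiated HUVEC with irradiated Jurkat (4 arrays) and irradiated HUVEC alone (2 arrays) at 1 h, with bars of 1 standard error from limma and filled points for the 11 genes that passed when adjusted over the list alone. All 22 differences are positive, with CCL2 at 2.53 and NFKBIA at 2.14.

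No single gene passed for the Jurkat partner over all genes: limma called 0 of 13709, with 715 at an unadjusted p under 0.05. Nearest was RASL10A, a Ras-like GTPase gene, at 2.17 ± 0.196 (adjusted p = 0.0528). It passed without HUVEC alone replicate 2 (2.22) and without co-culture replicate 2 (2.05), where the numbers of called genes were 24 and 6. SMAD6 at 2.93 ± 0.462 (adjusted p = 0.432) and CXCL1 also passed without co-culture replicate 2, at 3.33 and 2.63. Lowest were FAM110D at -1.40 ± 0.169 and DEPP1, a FOXO target, at -3.06 ± 0.464, not passing. Of genes of activated endothelium, SELE was at 2.64 ± 0.782 and ICAM1 at 1.56 ± 0.4, neither passing. T cell markers were higher by 0.90 (10 of 13, adjusted p = 0.0176, or 0.772 with an estimated correlation). Endothelial markers were lower, at -0.66 (17 of 18, adjusted p = 0.000148, or 0.772 with an estimated correlation). The T cell value was -0.02 without HUVEC alone replicate 1, 2.61 without its replicate 2, 0.43 without co-culture replicate 2 and 1.43 without co-culture replicate 4, and the endothelial value was -0.41 without HUVEC alone replicate 1 and -0.35 without co-culture replicate 2. T cell activation genes were higher by 1.04 (6 of 7, adjusted p = 0.0296, or 0.719 with an estimated correlation), with NFATC1 at 0.56 ± 0.123 past adjustment over the list alone, and the list was at 0.10 without HUVEC alone replicate 1, at 1.98 without its replicate 2 and, no longer called, at 1.12 without co-culture replicate 4. Smaller shifts were called for S phase genes at 0.20 (adjusted p = 0.00159), immediate early genes at 0.27 (adjusted p = 0.0451) and p53 targets at -0.25 (adjusted p = 0.0171), with adjusted p = 0.772, 0.772 and 0.785 with an estimated correlation. Without co-culture replicate 2 the S phase value was 0.090 and the p53 value -0.092, neither called, and the immediate early value 0.42. The p53 call was also lost without HUVEC alone replicate 2 (-0.32). Over 18 alternatives the p53 value lay between -0.60 and -0.042. The immediate early call was lost without HUVEC alone replicate 2 (0.24) and without co-culture replicates 1 (0.26), 3 (0.20) or 4 (0.19), and the value was -0.0086 after quantile normalization. Over all alternatives the calls were lost in 5 of 17 for T cell markers, 5 of 18 for T cell activation, 4 of 18 for S phase genes, 10 of 18 for immediate early genes and 7 of 18 for p53 targets. With the marker score as a covariate T cell activation genes were at 0.29, S phase genes at 0.024 and p53 targets at -0.042, none called.

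The co-culture with only HUVEC irradiated (1 array) differed from those with neither irradiated (2 arrays) first of all in cell markers. Of 18 endothelial markers 17 were lower, all 17 also when adjusted over the list alone, with a mean of -2.27 (adjusted p = 4.46e-07, or 0.722 with an estimated correlation). All 13 T cell markers were higher by 3.15 (adjusted p = 0.00815, or 0.771 with an estimated correlation). Genes of endothelial activation were lower, at -2.03 (15 of 16, 10 adjusted over the list alone, adjusted p = 2.93e-05, or 0.412 with an estimated correlation), among them the collagenase gene MMP1 at -3.90 ± 0.84 and ANGPT2 at -3.23 ± 0.651. TGF-beta and BMP targets were lower, at -1.90 (10 of 11, 8 adjusted over the list alone, adjusted p = 0.00136, or 0.711 with an estimated correlation). Immediate early genes were lower, at -0.995 (18 of 23, 8 adjusted over the list alone, adjusted p = 0.00559, or 0.722 with an estimated correlation). S phase genes were higher by 0.71 (24 of 24, adjusted p = 2.93e-05, or 0.722 with an estimated correlation). DNA repair genes were higher by 0.42 (17 of 22, adjusted p = 0.0451, or 0.722 with an estimated correlation). Over all genes 1 rose and 3 fell of 13662, with 4696 at an unadjusted p under 0.05 and 3091 at a false discovery rate of 10%. The count was 3571 in a fit of the compared groups alone (1465 higher and 2106 lower) and 4703 with array weights (2126 higher and 2577 lower). ACLY, which encodes ATP citrate lyase, was at -4.13 ± 0.226 (adjusted p = 0.00112) and LINC00482 at -3.68 ± 0.233 (adjusted p = 0.00175). CYB5R4 at 3.43 ± 0.354 and TTLL7 at -2.28 ± 0.236 (adjusted p = 0.0372 for both) lost their calls without non-irradiated replicate 1 (3.35 and -2.38) or 2 (3.50 and -2.18), and without replicate 1 the count was 2. The DNA repair call was lost without replicate 2 (0.42) and in 8 of 13 alternatives in all. The single array is of date B and the others of date D. Also of date B is 1 array with both irradiated, replicate 2, so that a term for date B could be fitted. The term rests on replicate 2, which had T cell markers at 4.79 and endothelial markers at -1.71. Its correlation with the single array was 0.929. The term cannot tell date from cell content, and calls that stay with it give no separate support. With this term endothelial markers were at -1.03, endothelial activation genes at -1.22, TGF-beta and BMP targets at -0.71, immediate early genes at -0.40 and S phase genes at 0.26, all still called. T cell markers at 1.26 and DNA repair genes at 0.19 were then not called, and 0 genes rose and 2 fell. The S phase call was lost with the marker score as a covariate (0.21), and the T cell call also with only probes valued on all 18 arrays (1.89).

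With Jurkat also irradiated (4 arrays against the same 1 array), p53 targets were higher by 0.85 (23 of 27, 12 adjusted over the list alone, adjusted p = 1.97e-06, or 0.687 with an estimated correlation), with GDF15 at 2.48 ± 0.553, the kinase gene PLK2 at 2.34 ± 0.575 and the cyclin-dependent kinase inhibitor gene CDKN1A at 1.85. The single array had a p53 target mean of -0.43, below the -0.09 and -0.06 of the co-cultures with neither irradiated, so part of the difference lies in that array. The p53 change was 0.53 with the marker score as a covariate, still called. With a term for date B it was 0.38. That term reduces the comparison to replicate 2 minus the single array, the 1 array against 1 within date B given below. It adds no separate support. All 13 T cell markers were lower, at -1.63, not called (adjusted p = 0.074). Endothelial markers were higher by 1.55 (17 of 18, adjusted p = 7.29e-07, or 0.722 with an estimated correlation). Endothelial activation genes were higher by 1.65 (16 of 16, 11 adjusted over the list alone, adjusted p = 1.97e-06, or 0.247 with an estimated correlation). TGF-beta and BMP targets were higher by 1.51 (11 of 11, 6 adjusted over the list alone, adjusted p = 0.000687, or 0.687 with an estimated correlation) and immediate early genes by 0.97 (19 of 23, 8 adjusted over the list alone, adjusted p = 0.000251, or 0.687 with an estimated correlation). NF-kB targets were higher by 0.84 (15 of 22, 7 adjusted over the list alone, adjusted p = 0.017, or 0.772 with an estimated correlation). S phase genes were lower, at -0.54 (24 of 24, adjusted p = 3.44e-05, or 0.735 with an estimated correlation). DNA repair genes were at -0.33 (17 of 22, adjusted p = 0.0451, or 0.722 with an estimated correlation) and G2/M genes at -0.25 (19 of 23, adjusted p = 0.0327, or 0.772 with an estimated correlation). Within date B, 1 array against 1, the changes were 0.38 for p53 targets (22 of 27 higher), 0.63 for endothelial markers, 1.04 for endothelial activation, 0.62 for TGF-beta and BMP targets, 0.52 for immediate early genes, 0.38 for NF-kB targets and -0.21 for S phase genes. Over all genes 2 rose and 1 fell of 13663, with 3047 at an unadjusted p under 0.05: ACLY at 3.82 ± 0.206 (adjusted p = 0.000999), LINC00482 at 3.59 ± 0.213 (adjusted p = 0.00103) and CAPS at -2.04 ± 0.208 (adjusted p = 0.0452). All 3 lost their calls in a fit of the compared groups alone, and CAPS also without replicates 1 (-1.99), 3 (-2.10) or 4 (-2.04). Without replicate 2, the other array of date B, 3318 genes passed, among them GDF15 at 2.85 and PLK2 at 2.73, and with array weights 3068. Leaving out replicate 2 sets arrays of date D against 1 array of date B, so that date and Jurkat irradiation cannot be told apart. The DNA repair call was lost without replicates 3 (-0.29) or 4 (-0.30) and the G2/M call without replicate 2 (-0.28). Over 15 alternatives these calls were lost in 10 and 5.

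In the 4 Jurkat-first co-cultures, irradiating Jurkat lowered genes of G2 and mitosis. All 23 measured members were lower, with a mean of -0.62 (adjusted p = 2.36e-17, or 0.051 with an estimated correlation), and 7 passed when adjusted over the list alone. Among these were CENPA, the centromeric histone, at -1.63 ± 0.292, the mitotic kinesin genes KIF20A at -1.42 ± 0.308 and KIF23 at -1.06 ± 0.176, and the mitotic kinase gene AURKA at -1.32 ± 0.187. The list's mean was -0.82 and -0.63 on the arrays with irradiated Jurkat, -0.02 and -0.20 on those without, and -0.55 in Jurkat irradiated alone. It lay between -0.79 and -0.62 over 11 alternatives. p53 targets were higher by 0.29 (22 of 27, adjusted p = 0.001, or 0.746 with an estimated correlation), with BBC3 at 1.96 ± 0.281 past adjustment over the list alone. Immediate early genes were higher by 0.42 (18 of 21, adjusted p = 0.000356, or 0.687 with an estimated correlation, 0 over the list alone). Endothelial markers were at -0.05 and T cell markers at -0.22, neither called. Over all genes 3 rose and 4 fell of 13026, with 775 at an unadjusted p under 0.05. This balance depended on the processing: 20 rose and 63 fell after quantile normalization, 3 and 30 with only probes valued on all 18 arrays, 13 and 74 with the date as a random block, 25 and 127 with a term for date B, 11 and 87 with array weights, 22 and 129 with the marker score as a covariate, 23 and 123 with arrays of date D alone, and 323 and 253 with zeros kept as values. STING1, the adaptor of cytosolic DNA sensing, was at -1.55 ± 0.135 (adjusted p = 0.0128) and ZNRF2P1 at 2.29 ± 0.223 (adjusted p = 0.0174). PLEKHA5 at 3.77 ± 0.286 (adjusted p = 0.00663) and ACOX2 at 2.31 ± 0.216 (adjusted p = 0.0164) were both at 0.16 and no longer called when only probes valued on all 18 arrays were averaged. Each of these groups has 1 array, whose spread is borrowed from the HUVEC-first arrays.

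Irradiating HUVEC in the same 4 co-cultures moved no list past the threshold. p53 targets were at 0.09 (adjusted p = 0.664). Hypoxia and glycolysis genes were at 0.14 (8 of 16 higher, adjusted p = 0.16), where BNIP3, a mitophagy receptor gene, at 1.06 ± 0.226 passed when adjusted over that list alone. The list's mean was 0.46 on the array with only HUVEC irradiated, against 0.21, 0.19 and 0.20 with neither, only Jurkat and both irradiated, so the shift lay in 1 array. That array correlated at 0.691, 0.722 and 0.677 with the others, which correlated at 0.802 to 0.844 with each other. Over all genes 8 rose and 2 fell of 13026, with 573 at an unadjusted p under 0.05. With zeros kept as values the balance turned, to 207 that rose and 308 that fell. It was 25 and 14 after quantile normalization, 28 and 8 with the date as a random block, 89 and 16 with a term for date B, 50 and 11 with array weights, 98 and 23 with the marker score as a covariate, and 84 and 15 with arrays of date D alone. BLVRA, which encodes biliverdin reductase A, was at 2.68 ± 0.219 (adjusted p = 0.00895), DNAAF9 at 2.37 ± 0.29 (adjusted p = 0.0479) and the small GTPase gene RAB43 at -1.99 ± 0.228 (adjusted p = 0.0377). TMEM71 at 4.45 ± 0.506 (adjusted p = 0.0377), ZNF703 at 3.04 ± 0.362 (adjusted p = 0.0436) and NRSN2 at 1.83 ± 0.187 (adjusted p = 0.0315) were called too. With only probes valued on all 18 arrays these were at 2.27, 0.11 and 0.37 and no longer called.

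The response to irradiation of both cell types differed between HUVEC-first and Jurkat-first co-cultures at 1 h in 5 lists, all tested as an interaction. The G2/M response was less negative in HUVEC-first co-cultures by 0.37 (22 of 23, adjusted p = 0.000242, or 0.703 with an estimated correlation). The p53 response differed by 0.16, not called (adjusted p = 0.105). DNA repair genes differed by 0.30 (19 of 22, adjusted p = 0.0263, or 0.722 with an estimated correlation). Immediate early genes differed by -0.45 (14 of 21 lower, adjusted p = 0.0368, or 0.765 with an estimated correlation). Endothelial markers differed by -0.82 (14 of 17 lower, adjusted p = 0.00433, or 0.802 with an estimated correlation). T cell markers differed by 1.68 (12 of 12, adjusted p = 0.0417, or 0.785 with an estimated correlation). The DNA repair call was lost in 5 of 18 alternatives, among them without irradiated replicate 2 (0.24) and with the marker score as a covariate (0.18). The immediate early call was lost in 8 of 18, among them without non-irradiated replicate 1 (-0.25), and the endothelial call in 2 of 17, quantile normalization (-0.57) and only probes valued on all 18 arrays (-0.71). The T cell call was lost in 8 of 17, among them without irradiated replicates 1 (1.61) or 2 (1.27) or non-irradiated replicate 1 (1.35), and the endothelial value was -0.48 without irradiated replicate 2. limma called 0 of 13255 genes, with 520 at an unadjusted p under 0.05, and 1 gene without non-irradiated replicate 2. ZNRF2P1 at -3.63 ± 0.37 came nearest (adjusted p = 0.0947), and the nuclear RNA NEAT1 was at 3.28.

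Irradiated HUVEC alone (2 arrays) differed from irradiated Jurkat alone (1 array) at 1 h in 207 of 13254 genes, 29 higher and 178 lower, with 1594 at an unadjusted p under 0.05. The balance depended on the processing: 255 were higher and 249 lower with zeros kept as values, and 261 and 680 after quantile normalization. All differences here are between ratios to the reference, and compare levels in the cells only if both arrays had the same reference. The integrin gene ITGB3 was at -5.36 ± 0.47 (adjusted p = 0.00228), ZNRF3, a ubiquitin ligase gene of Wnt signalling, at -5.38 ± 0.287, and FCGBP at 4.96 ± 0.492 (adjusted p = 0.00353). CYCSP52 at 6.90 and SERPINA9 at 4.68 lost their calls without HUVEC replicate 2 (5.74 and 3.52). The count was 131 without HUVEC replicate 1 and 107 without replicate 2, and a fit of these groups alone called 0 genes by limma. The ratios of G2/M genes were higher on the HUVEC arrays by 0.40 (19 of 23, adjusted p = 3.47e-05, or 0.687 with an estimated correlation). Those of ribosomal protein genes were higher by 0.28 (15 of 16, adjusted p = 0.00137, or 0.719 with an estimated correlation). p53 targets differed by 0.17 (16 of 27 higher, 4 up and 1 down adjusted over the list alone, with FAS at 1.72 ± 0.321 also over all genes, adjusted p = 0.0451, or 0.802 with an estimated correlation), a call lost without HUVEC replicate 1 (0.098) and in 7 of 14 alternatives in all. FAS lost its call without replicate 1 (1.78) or 2 (1.65). The ratios of T cell markers were higher on the HUVEC arrays by 2.09 (10 of 12, adjusted p = 0.0326, or 0.785 with an estimated correlation), and by 0.10 without HUVEC replicate 2, with the call lost in 6 of 14 alternatives. Of 24 endothelial markers 13 were exactly 0 on Jurkat alone, and over the 11 measured on Jurkat alone and on both HUVEC arrays the median difference was -0.155.

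HUVEC-first and Jurkat-first co-cultures, averaged over both and neither irradiated at 1 h (6 arrays against 2), differed in 2320 of 13255 genes, 858 higher and 1462 lower, with 4437 at an unadjusted p under 0.05. These too are differences between ratios to the reference. The count was 1362 without non-irradiated HUVEC-first replicate 1 and 1111 without replicate 2. JCAD, an endothelial junction protein gene, was at -7.40 ± 0.363 (adjusted p = 2.84e-05), MMP1 at -7.13 ± 0.568 (adjusted p = 0.000195) and RDX, which encodes the membrane linker radixin, at -7.01 ± 0.269 (adjusted p = 1.06e-05). Higher were HLA-DRB5, an MHC class II gene, at 7.09 ± 1.2 (adjusted p = 0.00993), the B cell receptor gene CD79B at 4.96 ± 0.474 (adjusted p = 0.000896), and POU2AF1 at 8.14 ± 1.92 (adjusted p = 0.0246) and JCHAIN at 6.90 ± 1.65 (adjusted p = 0.0261), both expressed in B-lineage cells. The calls of POU2AF1 and JCHAIN were lost without non-irradiated HUVEC-first replicate 1 (8.14 and 7.11) or 2 (8.14 and 6.69), and that of JCHAIN also without irradiated replicate 1.

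As lists, endothelial markers were lower in HUVEC-first co-cultures, at -1.79 (15 of 17, 11 adjusted over the list alone and 9 over all genes, adjusted p = 2.93e-05, or 0.746 with an estimated correlation), with CAV1 at -4.28 ± 0.413 and VWF at -3.37 ± 0.482. Endothelial activation genes were lower, at -1.76 (8 down and 2 up over all genes, adjusted p = 0.00791, or 0.687 with an estimated correlation), the adhesion genes VCAM1 at 2.94 ± 0.352 and ICAM1 at 2.77 ± 0.383 being the 2 that passed upward. With zeros kept as values the list was at -0.96 and not called. NF-kB targets were higher by 1.39 (15 of 20, 11 adjusted over the list alone and 8 over all genes, adjusted p = 0.000516, or 0.722 with an estimated correlation), with TNF at 5.78 and TNFAIP3 at 2.85 ± 0.495. Myeloid and B cell markers were higher by 2.77 (7 of 8, adjusted p = 0.0214, or 0.24 with an estimated correlation). T cell markers were higher by 2.15 (11 of 12, adjusted p = 0.0327, or 0.785 with an estimated correlation). Over 17 alternatives these calls were lost in 3 and 6. Myeloid and B cell markers were at 1.21 with only probes valued on all 18 arrays and 1.95 with zeros kept as values, neither called. Without irradiated replicate 2 both calls were lost, at 2.69 and 1.95, and the T cell call also without non-irradiated replicate 2 (1.97), with only probes valued on all 18 arrays (1.88) and after quantile normalization (2.10). Ribosomal protein genes were higher by 0.41 (14 of 16, 7 over all genes, adjusted p = 0.000142, or 0.687 with an estimated correlation). G2/M genes were higher by 0.33 (18 of 23, 5 over all genes, adjusted p = 0.00342, or 0.735 with an estimated correlation).

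Non-irradiated HUVEC-first co-cultures at 4 h (2 arrays) differed from those at 1 h (2 arrays) in 3799 of 13660 genes, 1673 higher and 2126 lower, with 5571 at an unadjusted p under 0.05. Leaving out 1 array gave 1271 and 1240 without 1 h replicates 1 and 2, and 2192 and 2026 without 4 h replicates 1 and 2. Each time point has its own date, so time and date cannot be told apart. NF-kB targets were lower at 4 h, at -1.39 (21 of 22, 8 over all genes and 8 adjusted over the list alone, adjusted p = 0.00327, or 0.746 with an estimated correlation). TGF-beta and BMP targets were lower, at -1.94 (11 of 11, 6 over all genes, adjusted p = 0.00275, or 0.722 with an estimated correlation). G2/M genes were lower, at -0.80 (20 of 23, 14 over all genes, adjusted p = 2.93e-05, or 0.687 with an estimated correlation), with the mitotic kinase genes AURKB at -1.64 ± 0.219 and AURKA at -1.58 ± 0.189. p53 targets were higher by 0.57 (19 of 27, 7 up and 2 down over all genes, 8 and 2 adjusted over the list alone, adjusted p = 0.0189, or 0.785 with an estimated correlation), with BBC3 at 3.25 ± 0.282 (adjusted p = 0.00135), GDF15 at 2.64 ± 0.494 and MDM2 at 2.05 ± 0.308. After quantile normalization the p53 list was at 0.53 and no longer called. Ribosomal protein genes were lower, at -0.57 (14 of 16, 7 over all genes, adjusted p = 0.00342, or 0.722 with an estimated correlation). S phase genes were lower, at -0.44 (19 of 24, adjusted p = 0.0261, or 0.805 with an estimated correlation), a call lost without 4 h replicate 2 (-0.30) and after quantile normalization (-0.36). The largest changes of single genes included the integrin gene ITGB4 at 6.23 ± 0.62 (adjusted p = 0.00152), DEPP1 at 5.84 ± 0.536 (adjusted p = 0.00137), MMP1 at -5.52 ± 0.686 (adjusted p = 0.00217), the metallothionein gene MT1G at -4.08 ± 0.483 (adjusted p = 0.00198) and the immediate early gene FOSB at -3.78 ± 0.516 (adjusted p = 0.00272). Endothelial markers were at -0.43 and T cell markers at 0.42, neither called. The 4 h arrays differed in other cell markers: the measured genes of CD79A, CD79B, MS4A1, PAX5 and CD22, all B-lineage genes, had means of 5.59 and 0.61 on replicates 1 and 2 at 4 h, against 4.11 and 3.64 at 1 h.

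A pair of comparisons had 1 array on each side and give values with no test. Adding irradiated HUVEC to irradiated Jurkat at 1 h, 1046 of 13094 genes differed by at least 2-fold, 659 higher and 387 lower, with PPARG, the adipogenic nuclear receptor gene, at 4.87 and CTNND2 at -3.46. After quantile normalization the balance turned, to 477 higher and 729 lower. Endothelial activation genes had a median of 0.44 (7 of 12 higher), above 98.8% of random lists of the same size, matched on the mean ratio of the genes. Such percentiles treat genes as independent and are not adjusted for the number of lists, so they describe the lists and test nothing. Adding irradiated Jurkat to irradiated HUVEC at 4 h, 1711 of 13556 genes differed by at least 2-fold, 887 higher and 824 lower, across dates A and C. The T cell receptor component gene CD3D was at 4.38, MMP1 at -5.29 and FOSB at -4.62. The median of TGF-beta and BMP targets was -1.32 and that of G2/M genes -0.55, each above only 0.01% of random lists. The median of endothelial activation genes was -0.70 (12 of 16 lower, above 0.05% of random lists). That of immediate early genes was -0.46 (above 0.18%), and that of interferon response genes was 0.46, above 99.7%.

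Some lists were called in no tested comparison. Over the 12 comparisons the mean change of hypoxia and glycolysis genes lay between -0.22 and 0.14 (smallest adjusted p = 0.16), that of interferon response genes between -0.12 and 0.48 (smallest adjusted p = 0.137), that of mesenchymal markers between -1.52 and 1.67 (smallest adjusted p = 0.0563) and that of sterol synthesis genes between -0.13 and 0.37 (smallest adjusted p = 0.0566).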

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

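All tests of explanations in this part were chosen after the result was seen. The differences between responses themselves were planned.

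In the group of 4 HUVEC-first arrays with both cell types irradiated at 1 h, 62 values were examined for 1 array far from the other 3, and 3 were found where chance would give 3.1. C6 was at 7.55 on replicate 4 against 6.67 to 6.70 on the others, FAM110D at -1.89 on replicate 3 against -2.04 to -2.02, and SMAD6 at 2.03 on replicate 2, the array of date B, against 3.54 to 3.72. Each gap divided by the range of the group, 0.959, 0.891 and 0.897, exceeded Dixon's critical value for 4 arrays. No explanation was tested for these.

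The response to irradiation of both cell types differed between 4 h and 1 h in endothelial markers by 1.02, in G2/M genes by 0.53, in myeloid and B cell markers by -1.87 and in p53 targets by -0.48. It differed between HUVEC-first and Jurkat-first co-cultures in DNA repair genes by 0.30, in endothelial markers by -0.82, in G2/M genes by 0.37, in immediate early genes by -0.45 and in T cell markers by 1.68. These are interaction tests of lists, and with an estimated correlation none of them stayed past the threshold.

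The smaller p53 response at 4 h went with p53 targets as high without irradiation as with it: the 2 non-irradiated co-cultures had means of 0.51 and 0.52 and the irradiated one 0.53, while the non-irradiated mean was negative on both arrays at 1 h. An exchange of an irradiated and a non-irradiated array would leave 2 of the 3 near the 1 h level without irradiation, but the lowest of the 3 was 0.509. A different share of T cells or of myeloid and B cells as the whole cause is argued against by the 2 non-irradiated arrays at 4 h. They lay on opposite sides of those at 1 h in T cell markers (1.88 and 0.41 against 0.84 and 1.25) and in myeloid and B cell markers (2.76 and 0.08 against 1.33 and 1.98), yet each alone was above those at 1 h in p53 targets, by 0.581 and 0.565. Other changes of the cell mixture stay open. With the marker score as a covariate the shift of 0.573 was 0.624, but that score differed less between the times than between the arrays at 4 h, so the adjustment decides nothing. A difference between dates may account for it and cannot be told apart from time, since all 3 co-culture arrays at 4 h share 1 date, and the shift of 0.573 is the same number under both. A rise of p53 targets with time in culture stays open as an untested biological explanation. The remaining array at 4 h, HUVEC irradiated alone of date C, had a p53 target mean of 0.28. Its counterparts at 1 h, of date D, were at 0.77 and 0.62, so it showed no rise with time. It is 1 irradiated array of other cells and another date, and decides nothing for the non-irradiated co-cultures.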

How the results depend on the processing

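The alternatives with zeros kept as values, date D only, centring on probes never at 0 and the doubted arrays (date B and HUVEC alone replicate 2) left out were chosen after the data had been seen. Values as deposited are identical to the centred ones, because every array has a median of 0, so that alternative tests nothing. No paired analysis was possible because the labels pair no samples. Fits of the compared groups alone for the main effects in Jurkat-first co-cultures, with 0 residual degrees of freedom, and the date as a fixed term for the time comparison, where it is not estimable, were not run. In comparisons whose only array of date B is irradiated co-culture replicate 2, the date B term is the same fit as leaving that array out. Both repeats are left out of the tallies in this paragraph and of all numbers of alternatives. Called genes listed by setting below do include the date B term. Of gene changes 4867 kept direction and side of the threshold, 191 lost and 206 gained a call and 6 reversed; of list shifts 833, 127, 0 and 5; of untested differences 12 stayed within the spread and 8 moved.

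Numbers of called genes that moved by more than 1.5 times, or from 0, are given by setting. Quantile normalization gave 2 for only HUVEC irradiated, 83 and 39 for irradiation of Jurkat and of HUVEC in Jurkat-first co-cultures, 941 for HUVEC alone against Jurkat alone and 3906 for HUVEC-first against Jurkat-first. Only probes valued on all 18 arrays gave 1 for the Jurkat partner at 1 h and 33 for Jurkat irradiation. No minimum number of arrays gave 2 for only HUVEC irradiated. Fits of the compared groups alone gave 3571 for only HUVEC irradiated, and limma then called 0 for Jurkat also irradiated and for HUVEC alone against Jurkat alone. The date as a random block gave 1 for the Jurkat partner, 2 for only HUVEC irradiated, 87 and 36 for the effects in Jurkat-first co-cultures, 360 for the cells alone and 1033 for time. The date as a fixed term gave 6 for the Jurkat partner, 2 for only HUVEC irradiated, 152 and 105 for the effects in Jurkat-first co-cultures and 427 for the cells alone. Array weights gave 12 for both irradiated at 1 h, 2 for the Jurkat partner, 4703 for only HUVEC irradiated, 3068 for Jurkat also irradiated, 98 and 61 for the effects in Jurkat-first co-cultures, 2 for the response by order, 317 for the cells alone and 3732 by order. The marker score as a covariate gave 2 for only HUVEC irradiated, 151 and 121 for the effects in Jurkat-first co-cultures and 1 for the response by order. Zeros kept as values gave 1 for both irradiated at 1 h, 73 at 4 h, 49 for the difference between these, 3 for the Jurkat partner, 103 for only HUVEC irradiated, 110 for Jurkat also irradiated, 576 and 515 for the effects in Jurkat-first co-cultures, 202 for the response by order and 504 for the cells alone. Centring on probes never at 0 gave 19 for Jurkat irradiation. Arrays of date D alone gave 1 for the Jurkat partner, 146 and 99 for the effects in Jurkat-first co-cultures and 404 for the cells alone. Without the doubted arrays the Jurkat partner had 41. The estimated correlation left 0 list shifts and fry 4. The cause was not tested for any of these.

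Leaving out 1 array in turn gave 0 to 1 for both irradiated at 1 h, for the 4 h minus 1 h difference and for the response by order, 0 to 24 for the Jurkat partner, 2 to 3 for only HUVEC irradiated, 2 to 3318 for Jurkat also irradiated, 107 to 131 for the cells alone, 1111 to 3064 by order and 1240 to 2192 for time. Reversals were few. With the covariate, S phase genes with both irradiated at 1 h were at -0.052 and PRIM1 at -0.048. With quantile normalization, CCL3 was at -0.081 and immediate early genes at -0.0086 for the Jurkat partner. AKNA for the Jurkat partner was at 0.91 with probes valued on all arrays and 0.62 with zeros kept, where its average rests on the same probes on every array. TNFRSF4 was at -0.11 without the doubted arrays, and CD2 in the response by order at -0.31 with probes valued on all arrays. With 1 array left out in turn, myeloid and B cell markers lay between -2.58 and 0.50 at 4 h and between -2.86 and 0.11 for 4 h minus 1 h, and T cell markers for the Jurkat partner between -0.018 and 2.61. Signal over background is not given in the sources used here, so its limit on these values is unknown.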

Other observations

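All tests of explanations in this part were chosen after the result was seen.

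B-lineage genes were high on most HUVEC-first arrays. Over the measured ones of 5 such genes of the planned myeloid and B cell list, the means were 4.11 and 3.64 in the co-cultures with neither cell type irradiated at 1 h, between 4.17 and 5.18 with both irradiated, 5.18 with only HUVEC irradiated, and 2.06 and 4.56 in HUVEC irradiated alone. At 4 h they were 5.59 and 0.61 on the 2 non-irradiated arrays and 0.81 on the irradiated one, and at 1 h they were negative on every Jurkat-first array and on Jurkat alone. RNA of CD3-positive Jurkat cells as the whole source in the co-cultures with neither irradiated was not decided by the CD3 genes. The measured ones had a mean of 0.504 there beside a B-lineage mean of 3.85, but only 1 and 3 of the 4 CD3 genes had a value other than exactly 0 on these arrays. The wider T cell list argues against it for these arrays, if the HUVEC-first arrays share a reference, though zeros limit this list too. The median of its 22 markers, zeros included, was 0.159 and 0.53 there, with 8 and 5 of them at exactly 0. The means, zeros included, were 0.84 and 1.25. The B-lineage means leave zeros out, so the sizes of the 2 lists cannot be compared directly. With both irradiated, at similar B-lineage levels, the median was 3.75, 4.96, 2.86 and 0.682 on replicates 1 to 4, with 0, 0, 1 and 6 markers at 0. RNA of B-lineage cells in the samples may be the source: a second list of 20 B-lineage genes had a median of at least 4.30 on each 1 h HUVEC-first co-culture, and of at least 2.90 over the 14 of these genes whose values had not been looked at before. PAX5, which is in the first list only, does not go with this: it was exactly 0 on every HUVEC-first array and on HUVEC alone, except at -0.52 on replicate 2 with neither irradiated at 1 h, and was measured on Jurkat alone at 0.84. On Jurkat alone 100% of the second list had a value other than exactly 0, which may come from the sample or the reference. The median ratio was -0.10 there and between -0.27 and -0.16 on the Jurkat-first co-cultures. If all arrays share a reference, these values argue against the cells labelled Jurkat as the source. If the reference differs between arrays, that explanation stays open. No biological explanation was tested.

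Markers of the named cell type lay near 0 on arrays of that cell type alone. The tests of marker differences and of zeros decided none of 3 explanations. One reference holding RNA of both cell types on every array would put endothelial markers far higher in HUVEC alone than in Jurkat alone, and exchanged labels under one reference far lower. The median difference was -0.155, with quartiles of -0.438 and 0.042. It rests on the 11 of 24 markers with a value on all 3 arrays, and those that Jurkat lacks may be left out. Under one reference a mixture would lie between its parts. Endothelial marker means, zeros included, were 0.84 to 1.17 on the Jurkat-first co-cultures. HUVEC alone gave 0.10, -0.44 and -0.21, and Jurkat alone 0.15. These values argue against both one-reference explanations, if co-culture itself did not raise the markers. A reference made of the first-named cell type on each array would go against the labels, which name a common pooled reference. It may explain why 13 of 24 endothelial markers were exactly 0 on Jurkat alone, where neither channel would then hold them, and at most 2 on an array of HUVEC alone. T cell markers did not mirror this: 7 of 22 were exactly 0 on Jurkat alone, against 10 and 0 on replicates 1 and 2 of HUVEC alone at 1 h and 7 at 4 h. With such a reference the differences between HUVEC-first and Jurkat-first arrays, and between HUVEC alone and Jurkat alone, would mix samples with references, and no biological explanation was tested.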
